A study of Homo sapiens with 4 samples.

How the data were processed

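RNA from RWPE-ETV1 and RWPE-GUS cells was measured on 4 two-colour Agilent whole human genome oligonucleotide arrays. Per the labels, total RNA was extracted with Trizol and purified on a silica column, and was amplified from a T7 promoter with incorporation of Cy3- or Cy5-labelled nucleotides. The arrays fell into 2 groups of 2 by dye orientation, with RNA labelled RWPE-ETV1 in Cy5 or in Cy3, and both orientations carry the replicate numbers 1 and 2. The direction of each ratio was taken from the dyes given in the labels.

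The deposited scanner files hold intensity values, the mean brightness of each spot and the median brightness of its local background in each channel, with no normalisation. Per the file headers, these came from Agilent Feature Extraction, whose version 9.1.3.1 is also named in the submitters' processing notes. Per the file headers, the same files give processed signal intensity that was background-subtracted, detrended and dye-normalised within the array by linear and LOWESS steps. The log10 ratio of Cy5 over Cy3 processed signals and its p-value from the scanner software's error model per spot are also given, per the file headers. The authors' deposited value table equals each array's log10 ratio exactly (largest difference 0), with dye swaps not turned and no centring, and is empty where that ratio was recorded as 0. Its column medians were 0.00615 and 0.00431 for replicates 1 and 2 with RWPE-ETV1 in Cy5 and 0.00589 and 0.0023 for those with it in Cy3, so its scale, centring and direction are known. It held 0 columns that could not be mapped to an array.

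Each array has 43376 gene spots and 1639 control spots. Median spot brightness over gene probes was between 185 and 229 in both channels and local background between 41 and 51. None of the gene spots (0) was saturated, and 25 spots flagged as non-uniform or population outliers were left out. In the scanner software's own statistics, spike-in controls gave a slope of observed on expected log ratio between 0.912 and 0.922, so that software's fold changes were somewhat compressed. No such slope was computed for the ratios fitted here. The number of arrays limits the precision.

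Background was corrected with normexp and an offset of 50 on mean spot and median background signals, and ratios were normalised within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. The offset pulls the ratios of dim probes toward 0. Spots of a probe were averaged. A probe was kept if it was well above background in the RNA labelled RWPE-ETV1 on all 4 arrays or in the RNA labelled RWPE-GUS on all 4, which left 26016 of 41000 probes. The kept probe with the highest mean brightness over both channels stood for its gene, which gave 13771 genes. Gene names were updated through a RefSeq gene table of assembly GRCh38.p14, used for names and for the order of neighbouring genes. The accession matched for 23434 probes, the current symbol for 2317 and a synonym for 1043. For 1653 probes the file's name was kept, and 12553 had no gene symbol and were tested only as probes.

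Ratios were turned to RWPE-ETV1 over RWPE-GUS and fitted with lmFit and eBayes in limma, with an ETV1 term and a dye term, which left 2 residual degrees of freedom per gene (prior degrees of freedom 10.2). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. Levels per cell line were taken per channel after loess and quantile normalisation of mean brightness between arrays. For a gene not well above background in 1 of the lines on every array, the fold is a lower bound, from the bright line's mean level against the higher of the dim probe's own level and the lowest level of probes well above background on each array.

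A set of 25 gene lists was fixed before the data were examined. They cover the ETS family, proteolysis and invasion, integrins and hemidesmosome, extracellular matrix, basal, luminal and squamous epithelial markers, epithelial junctions, mesenchymal markers, G2/M and DNA replication, MAPK feedback and EGFR ligands, cytokines and NF-kappaB targets, interferon response, TGF-beta targets, cholesterol synthesis, androgen and steroid metabolism, hypoxia and glycolysis, p53 targets, unfolded protein and amino acid stress, NRF2 targets, fibroblast, leukocyte and endothelial, and neuroendocrine markers, and housekeeping genes. Shifts of lists with at least 5 measured genes were tested with camera in limma at its preset correlation of 0.01 between genes, adjusted over the lists. Of the 6 lists that passed, 0 passed with an estimated correlation, a test that rests on the 2 residual degrees of freedom. The rule for named genes was also fixed before the data were examined. It takes ETV1, the 12 highest and 12 lowest called genes with the same direction on all 4 arrays, leaving out provisional symbols, up to 2 highest and 2 lowest members of each list among those that passed, and the members of proteolysis and invasion past 2-fold. Some genes that this rule takes are not reported here.

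The scripts were tested on simulated arrays built from the real brightness, spread and dye effects of these genes, with 200 of 13771 genes changed. For RWPE-ETV1 against RWPE-GUS, an adjusted p under 0.05 with the right direction was found for 90% of 50 genes changed 1.5-fold, 100% of 50 changed 2-fold, 98% of 50 changed 3-fold and 100% of 50 changed 4-fold. The median estimates were 0.57, 0.95, 1.55 and 1.94 on the log2 scale, and 20% of the genes changed 2-fold and 96% of those changed 3-fold reached the 2-fold minimum. Of 13571 unchanged genes, 0.0221% had an adjusted p under 0.05. The simulated noise was drawn independently for each array, with each gene's residual spread from the fit. It holds no error shared between arrays, and far fewer genes were changed than the 70.3% that passed in the real data. The simulation therefore does not give the error rate of the real calls. A list of 30 genes shifted by 0.5 passed camera, and an unshifted list of 30 did not (adjusted p = 0.407). With an estimated correlation the shifted list had an unadjusted p of 0.00602.

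Alternatives covered the background correction, the normalisation, the filter on dim probes, the dye term, the replicate number as a block, averaging same-numbered arrays, the rule for probes, the deposited value table, leaving out each array, the test and the thresholds. All 4 arrays lay on 1 slide and were scanned together, so no slide or scan block could be fitted, and dye orientation coincided with the place on the slide. Figures were drawn with matplotlib 3.10.9.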

Results

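Gene expression was compared between derivatives of RWPE, an immortalised line of benign human prostate epithelial cells. RWPE-ETV1 cells are described as stably expressing ETV1, a transcription factor of the ETS family, and RWPE-GUS cells as expressing beta-glucuronidase as a control. The comparison asks which genes change in benign prostate epithelial cells when ETV1 is overexpressed. RNA came from a single line of each kind, so no change below can be told apart from other differences between the lines. Untreated cells of both lines were grown in serum-free keratinocyte medium with bovine pituitary extract, epidermal growth factor and blasticidin, and RNA of both lines was hybridised together on each of 4 two-colour oligonucleotide arrays. RNA labelled RWPE-ETV1 carried Cy5 on 2 arrays and Cy3 on the other 2. After background correction and normalisation within each array, every ratio was turned so that a positive log2 change means more transcript in the RNA labelled RWPE-ETV1, and "rose", "higher", "fell" and "lower" below refer to that RNA relative to the RNA labelled RWPE-GUS. Of 41000 gene probes, between 62.0% and 71.7% were well above background in the RNA labelled RWPE-ETV1 and between 63.3% and 70.0% in the RNA labelled RWPE-GUS. The turned ratios correlated across genes at 0.96 and 0.94 between arrays of the same dye orientation and at 0.66 to 0.78 between arrays of opposite orientation. The number of arrays limits the precision. The labels do not say that the arrays came from separate cultures, so the spread between these 4 hybridisations may be technical. The dye term takes up differences between the orientations, so SEs and p-values measure only the spread between arrays of the same orientation.

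ETV1 itself was lower in the RNA labelled RWPE-ETV1. Probe A_23_P134366 gave a log2 change of -0.66 (SE 0.0449, adjusted p = 4.14e-07 over all kept probes in limma), a level 1.58-fold lower, with log2 ratios between -0.80 and -0.50 on the 4 arrays. Its log2 level was 7.49 ± 0.14 (SD, n = 4) in the RNA labelled RWPE-ETV1 and 8.15 ± 0.02 (SD, n = 4) in the RNA labelled RWPE-GUS. The other probe, A_32_P78491, gave -0.58 (SE 0.0440, adjusted p = 9.12e-07 in limma), a level 1.49-fold lower, and was well above background on 3 of the 4 arrays in the RNA labelled RWPE-ETV1. The files give no probe positions, so whether either probe lies within the expressed ETV1 sequence is unknown, and a probe outside it checks nothing. The values therefore go against the labels or say nothing about them, and every direction below rests on the labels alone. Neither probe shows overexpression of ETV1 in the RNA labelled RWPE-ETV1.

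**Figure D1:**
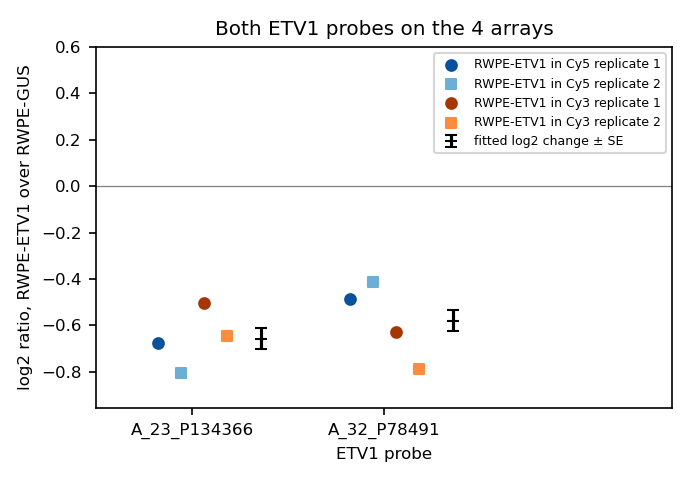
Log2 ratios of both ETV1 probes on each of the 4 arrays (points, coloured by array), with the fitted log2 change ± SE (bar) beside each probe; the vertical axis is the log2 ratio of RNA labelled RWPE-ETV1 over RWPE-GUS. Every point lies below 0, and the fitted values are -0.66 and -0.58.

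Of 13771 genes tested, 465 changed at least 2-fold at an adjusted p under 0.05 in limma, 179 higher and 286 lower, and 464 of them had the same direction on all 4 arrays. The exception was MT1X, measured on 3 arrays and lower on each. The highest was SCG5, which encodes the neuroendocrine chaperone 7B2, with a log2 change of 2.99 (SE 0.0479, adjusted p = 3.94e-13), or 7.95-fold. It was followed by SLC22A3, an organic cation transporter (2.73, SE 0.0419), the stromelysin gene MMP3 (2.59, SE 0.0470) and IGFBP3, a carrier of insulin-like growth factors (2.57, SE 0.0413). Next came G0S2, an inhibitor of lipolysis (2.38), the gelatinase gene MMP9 (2.38), CRYM (2.33), DRC11 (2.28), the matrix proteoglycan gene SPOCK1 (2.27), PLAU (2.19) and the metalloproteinase gene ADAM19 (2.11). The MMP9 and ADAM19 ratios of 1 array, replicate 1 with RWPE-ETV1 in Cy5, stood above those of the other 3.

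The lowest gene was CA9, the hypoxia-induced carbonic anhydrase, with a log2 change of -3.24 (SE 0.0427, adjusted p = 1.42e-13), or 9.46-fold lower. The linker histone gene H1-1 followed at -2.80 (SE 0.131), although its ratios on the 4 arrays ranged from -4.06 to -1.54. EGR1, an immediate-early transcription factor, was lower by 5.67-fold (-2.50, SE 0.0416) and ANKRD22 by 5.55-fold (-2.47, SE 0.0464). The remaining 8 were the condensin subunit gene NCAPG (-2.45), SAPCD2 (-2.39), the mitotic spindle gene HMMR (-2.30), the kinetochore gene NUF2 (-2.24), the replication initiation gene CDC45 (-2.22), PIMREG (-2.15), the mitotic kinesin gene KIF20A (-2.13) and TNFRSF6B, a soluble decoy receptor for Fas ligand (-2.07). CYP4B1 was the called gene that was not well above background in the RNA labelled RWPE-ETV1 on any array, and was at least 2.45-fold lower there (adjusted p = 3.06e-10 in limma).

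**Figure D2:**
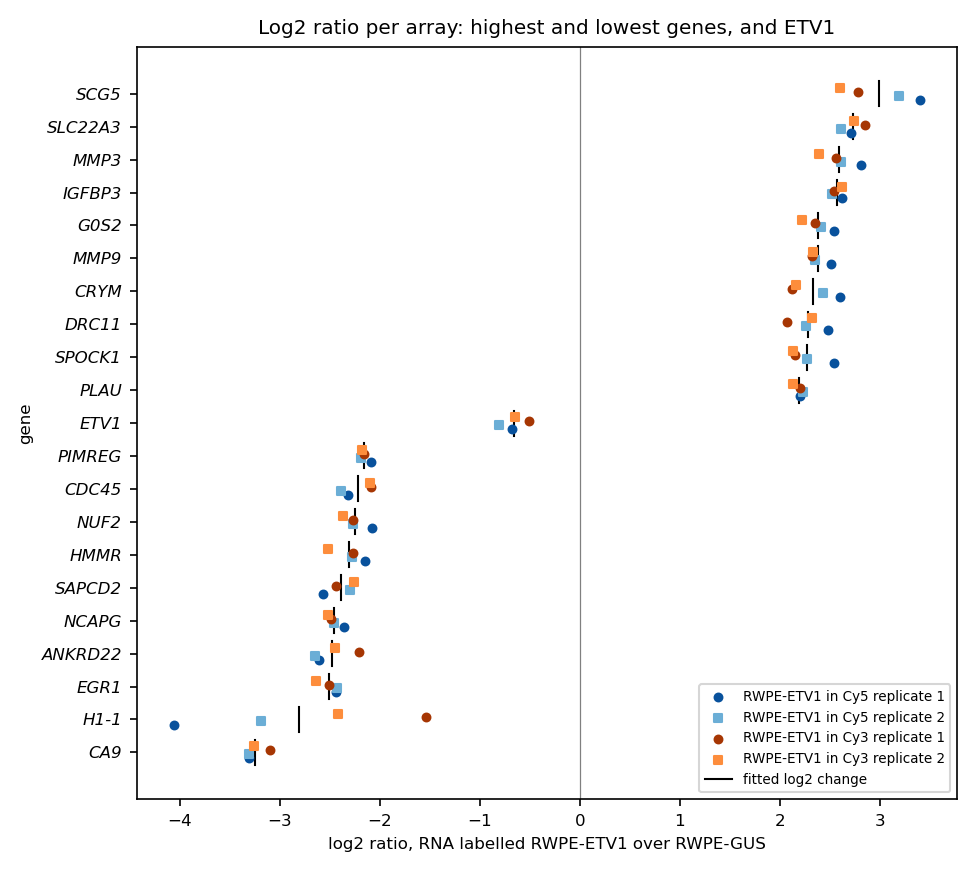
Log2 ratio of RNA labelled RWPE-ETV1 over RWPE-GUS on each of the 4 arrays (points, coloured by array) for the 10 highest and 10 lowest genes and ETV1, with the fitted log2 change as a vertical bar; the horizontal axis is in log2 units and each line of the vertical axis is a gene. SCG5 is highest at 2.99, CA9 lowest at -3.24, and the points of H1-1 spread from -4.06 to -1.54.

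Proteases and their regulators rose as a group. Of 27 measured genes of the proteolysis and invasion list, 22 rose, 2 fell and 3 did not pass, with a median log2 change of 0.63 (camera adjusted p = 3.84e-07 with the preset correlation). The adjusted p was 0.223 with an estimated correlation, and the median was 0.411 with no filter on dim probes and 0.417 with probes tested singly. Members past 2-fold included MMP3, IGFBP3, MMP9, PLAU and ADAM19, and SERPINE2, a serine protease inhibitor gene (1.07, 2.10-fold higher). PLAU encodes urokinase, a plasminogen activator, and was 4.57-fold higher (SE 0.0402). PLAT, the tissue plasminogen activator gene, fell 1.84-fold (-0.88, SE 0.0437), and S100A4 fell 1.68-fold (-0.75, SE 0.0416).

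Extracellular matrix genes also rose on balance, with 18 of 24 measured members higher, 5 lower and 1 that did not pass, and a median log2 change of 0.41 (camera adjusted p = 0.00112). The adjusted p was 0.55 with an estimated correlation. The collagen gene COL5A1 rose 3.79-fold (1.92, SE 0.0419) and the fibronectin gene FN1 3.49-fold (1.80, SE 0.0398). CCN2 fell 3.15-fold (-1.66, SE 0.0414) and CCN1 1.54-fold (-0.62, SE 0.0428); both encode matricellular proteins. Of 19 measured mesenchymal markers, 11 rose, 4 fell and 4 did not pass, with a median of 0.26 (camera adjusted p = 0.0277). The adjusted p was 0.613 with an estimated correlation, and 0.0613 when a probe had to be well above background in both channels of all 4 arrays. The median was 0.0977 with no filter on dim probes and 0.159 with probes tested singly. This list shares FN1 and LOXL2 with the matrix list, and S100A4 among others with the proteolysis list. The cadherin gene CDH11 rose 3.79-fold (1.92, SE 0.0565), and the receptor kinase gene AXL fell 1.75-fold (-0.81, SE 0.0412).

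Genes of cell division fell as a group. All 34 measured members of the G2/M list fell by at least 2-fold at the probe that stood for the gene, with a median log2 change of -1.65 (camera adjusted p = 2.6e-21). The adjusted p was 0.223 with an estimated correlation. For CCNB2, a member of this list, another kept probe passed in the opposite direction. HMMR was 4.93-fold lower (SE 0.0485) and KIF20A 4.36-fold lower (SE 0.0395). Of 39 genes of the DNA replication list, 36 fell, 1 rose and 2 did not pass, with a median of -0.66 (camera adjusted p = 2.84e-11). The adjusted p was 0.264 with an estimated correlation. CDC45 fell 4.66-fold (SE 0.0401) and the thymidine kinase gene TK1 3.99-fold (-1.99, SE 0.0403), while CCNE1, which encodes cyclin E, rose 1.46-fold (0.54, SE 0.0399). Members of these 2 lists made up 43 of the 286 called genes that fell.

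Feedback regulators of the MAPK pathway and epidermal growth factor receptor ligands fell as a group, with 21 of 26 measured genes lower, none higher and 5 that did not pass. The median log2 change was -0.43 (camera adjusted p = 5.25e-07), and the adjusted p was 0.223 with an estimated correlation. EGR1 was lowest, and FOS, another immediate-early gene, fell 3.95-fold (-1.98, SE 0.0438). Among 22 measured ETS family genes, 5 rose, 9 fell and 8 did not pass (median -0.07, camera adjusted p = 0.457). FLI1 rose 1.95-fold (0.96, SE 0.0407) and EHF, an epithelial ETS factor, rose 1.62-fold (0.69, SE 0.0412). ETV4, a close relative of ETV1, fell 2.08-fold (-1.06, SE 0.0468) and ELF3 fell 1.81-fold (-0.86, SE 0.0453). The ETV4 ratios were -1.48 and -1.26 with RWPE-ETV1 in Cy5 but -0.81 and -0.69 with it in Cy3.

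**Figure D3:**
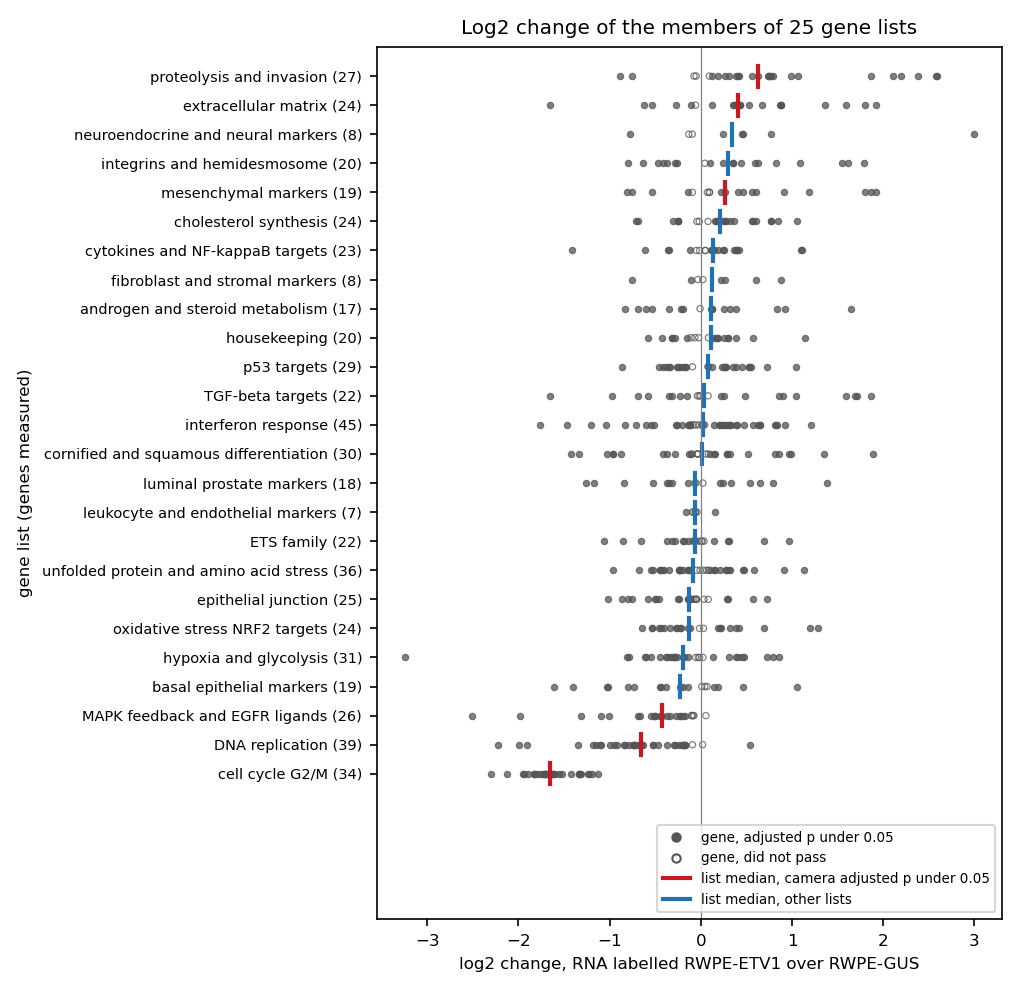
Log2 change, RNA labelled RWPE-ETV1 over RWPE-GUS, of the measured members of the 25 gene lists (horizontal axis, log2 units; 1 line per list with its number of measured genes). Filled circles are genes at adjusted p under 0.05, open circles did not pass, and vertical bars are list medians, red where camera's adjusted p with the preset correlation was under 0.05; the G2/M median lies at -1.65 and the proteolysis and invasion median at 0.63.

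Markers of epithelial identity moved in both directions, and no list of them passed camera. Over all 13771 genes, 4791 rose and 4893 fell at the same threshold, so list counts near these shares, here and below, say nothing particular about a list. Of 19 measured basal markers, 12 fell, 4 rose and 3 did not pass (median -0.23, camera adjusted p = 0.0707). The basal keratin genes KRT15 and KRT5 fell 3.05-fold (-1.61, SE 0.0400) and 2.65-fold (-1.40, SE 0.0402), whereas PDPN, the podoplanin gene, rose 2.08-fold (1.06, SE 0.0421) and BNC1 1.37-fold (0.46, SE 0.0395). This list passed camera when single arrays were left out: adjusted p = 0.037 without replicate 1 and 0.0418 without replicate 2 with RWPE-ETV1 in Cy5, and 0.0475 without replicate 2 with it in Cy3. With all 4 arrays and an estimated correlation the adjusted p was 0.623. Of 18 luminal prostate markers, 7 rose, 8 fell and 3 did not pass (median -0.06, camera adjusted p = 0.775). NDRG1 rose 1.74-fold (0.80, SE 0.0483). The keratin gene KRT19 fell 2.40-fold (-1.26, SE 0.0406) and FKBP5 2.26-fold (-1.17, SE 0.0666), with 1 array lower than the others for FKBP5.

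Of 25 epithelial junction genes, 14 fell, 4 rose and 7 did not pass (median -0.13, camera adjusted p = 0.0707). CLDN1, a tight junction claudin gene, fell 2.03-fold (-1.02, SE 0.0418) and the desmosomal gene PKP2 fell 1.83-fold (-0.87, SE 0.0548). The tight junction gene TJP1 rose 1.66-fold (0.73, SE 0.0455) and CDH1, the E-cadherin gene, 1.48-fold (0.57, SE 0.0419). Of 30 genes of squamous differentiation, 13 rose, 11 fell and 6 did not pass (median 0.01, camera adjusted p = 0.772), and the median turned to -0.0299 with no filter on dim probes. SPRR3, a cornified envelope precursor, rose 3.69-fold (1.88, SE 0.0415) and LCN2 2.54-fold (1.35, SE 0.0412), and the kallikrein genes KLK8 and KLK5 fell 2.69-fold (-1.43, SE 0.0428) and 2.52-fold (-1.34, SE 0.0413). Among 20 integrin and hemidesmosome genes, 12 rose, 7 fell and 1 did not pass (median 0.30, camera adjusted p = 0.142), and the median was 0.183 without replicate 2 with RWPE-ETV1 in Cy5. The laminin gene LAMA3 rose 3.05-fold (1.61, SE 0.0418), and the laminin gene LAMB3, picked after its value was seen, rose 2.92-fold (1.54, SE 0.0424). ITGB8 fell 1.74-fold (-0.80, SE 0.0404) and PLEC 1.55-fold (-0.63, SE 0.0473).

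Cytokine, interferon and TGF-beta genes were mixed. Of 23 cytokine and NF-kappaB target genes, 14 rose, 5 fell and 4 did not pass (median 0.13, camera adjusted p = 0.142). IL11 rose 2.15-fold (1.11, SE 0.0396) and IL32 2.14-fold (1.10, SE 0.0446), while TNFAIP2 fell 2.65-fold (-1.41, SE 0.0403) and IL18 1.53-fold (-0.61, SE 0.0425). Of 45 interferon-response genes, 21 rose, 16 fell and 8 did not pass (median 0.03, camera adjusted p = 0.545). The restriction factor gene BST2 rose 2.31-fold (1.21, SE 0.0404) and HLA-F 1.90-fold (0.92, SE 0.0405), and the interferon-induced genes OASL and IFIT2 fell 3.40-fold (-1.77, SE 0.0485) and 2.77-fold (-1.47, SE 0.0448). Of 22 TGF-beta targets, 10 rose, 8 fell and 4 did not pass (median 0.04, camera adjusted p = 0.44), and the median turned to -0.0017 with no filter on dim probes. INHBA, the activin A subunit gene, rose 3.27-fold (1.71, SE 0.0399), and ID1 fell 1.96-fold (-0.97, SE 0.0405) along with CCN2.

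Metabolic and stress lists did not pass camera either. Of 24 cholesterol synthesis genes, 15 rose, 6 fell and 3 did not pass (median 0.21, camera adjusted p = 0.0707). HMGCS1 rose 2.08-fold (1.06, SE 0.0406) and IDI1 1.80-fold (0.85, SE 0.0394), and ACAT2 and FDPS fell 1.63-fold (-0.71, SE 0.0398) and 1.61-fold (-0.69, SE 0.0396). Of 31 hypoxia and glycolysis genes, 18 fell, 9 rose and 4 did not pass (median -0.19, camera adjusted p = 0.152). Besides CA9, the glycolytic enzyme gene ENO1 fell 1.75-fold (-0.81, SE 0.0564), whereas P4HA2, a collagen prolyl hydroxylase subunit gene, rose 1.81-fold (0.85, SE 0.0425). Of 17 androgen and steroid metabolism genes, 9 rose, 7 fell and 1 did not pass (median 0.11, camera adjusted p = 0.775), and the median turned to -0.00765 with no filter on dim probes and with probes tested singly. The cytochrome P450 genes CYP1B1 and CYP1A1 rose 3.13-fold (1.65, SE 0.0408) and 1.90-fold (0.92, SE 0.0416), and SRD5A3 and HSD17B1 fell 1.78-fold (-0.83, SE 0.0398) and 1.61-fold (-0.69, SE 0.0416).

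Of 29 p53 targets, 14 rose, 12 fell and 3 did not pass (median 0.08, camera adjusted p = 0.545). TP53INP1 rose 2.07-fold (1.05, SE 0.0419) and CDKN1A, the p21 cell cycle inhibitor gene, 1.65-fold (0.72, SE 0.0428). PERP fell 1.37-fold (-0.45, SE 0.0402). Of 36 genes of the unfolded protein and amino acid stress list, 13 rose, 18 fell and 5 did not pass (median -0.08, camera adjusted p = 0.588). The endoplasmic reticulum chaperone gene HSPA5 rose 2.19-fold (1.13, SE 0.0432) and its cochaperone gene DNAJB9 1.88-fold (0.91, SE 0.0424), while the amino acid synthesis genes ASNS and PSPH fell 1.94-fold (-0.96, SE 0.0439) and 1.60-fold (-0.68, SE 0.0461). Of 24 NRF2 targets, 9 rose, 13 fell and 2 did not pass (median -0.13 against a mean of 0.01, camera adjusted p = 0.665). The heme oxygenase gene HMOX1 rose 2.43-fold (1.28, SE 0.0413) and the ferritin light chain gene FTL 2.29-fold (1.20, SE 0.0447), and TKT and AKR1B10 fell 1.57-fold (-0.65, SE 0.0466) and 1.45-fold (-0.53, SE 0.0406).

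Markers of other cell types were few above background. Of 7 measured leukocyte and endothelial markers, CD68 rose 1.12-fold (0.16, SE 0.0439), CD14 fell 1.12-fold (-0.16, SE 0.0421) and 5 did not pass (camera adjusted p = 0.588). With median centring neither CD68 nor CD14 passed (adjusted p = 0.108 and 0.241), and with no dye term neither did (0.0848 and 0.0677), and CD68 also missed the threshold without replicate 2 with RWPE-ETV1 in Cy5 (0.0749). Of 8 fibroblast and stromal markers, 4 rose, 2 fell and 2 did not pass (median 0.12, camera adjusted p = 0.457), and the median turned to -0.0103 with no filter on dim probes. COL1A1 rose 1.83-fold (0.88, SE 0.0415) and TWIST1 1.52-fold (0.61, SE 0.0448), with 1 array lower than the other 3 for TWIST1, and S100A4 fell. FBLN1 also passed as lower (-0.11, SE 0.0436), but it was higher on 1 of the 4 arrays and no longer passed when any of 3 arrays was left out (adjusted p between 0.0913 and 0.216). Of 8 neuroendocrine and neural markers, 5 rose, 1 fell and 2 did not pass (median 0.34, camera adjusted p = 0.149), and with no filter on dim probes the shift vanished (median -1.61e-05). Besides SCG5, the ubiquitin hydrolase gene UCHL1 rose 1.71-fold (0.77, SE 0.0395), and the tubulin gene TUBB3 fell 1.72-fold (-0.78, SE 0.0498). Of 20 housekeeping genes, 10 rose, 6 fell and 4 did not pass (median 0.11, camera adjusted p = 0.561). The transferrin receptor gene TFRC rose 2.21-fold (1.14, SE 0.0410) and the actin gene ACTB 1.49-fold (0.58, SE 0.0436), and HPRT1 and GAPDH fell 1.49-fold (-0.58, SE 0.0443) and 1.35-fold (-0.43, SE 0.0497). The ACTB ratios were 1.12 and 0.95 with RWPE-ETV1 in Cy5 but 0.16 and 0.08 with it in Cy3, and ACTB missed the threshold with no dye term (adjusted p = 0.0533). Those of GAPDH were -0.83 and -0.60 with RWPE-ETV1 in Cy5 but -0.24 and -0.05 with it in Cy3. For HPRT1 they were -0.29 and -0.35 with RWPE-ETV1 in Cy5 but -0.74 and -0.93 with it in Cy3.

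Every log2 change above comes from limma with an ETV1 term and a dye term over the 4 arrays, and each gene given as risen or fallen had an adjusted p under 0.05 over the 13771 genes. ETV4, NDRG1, BST2, ASNS and KLK5, among others, also passed the dye term (adjusted p from 0.00013 to 0.00038 in limma), as 5971 genes did. Their fitted values average unlike ratios of the 2 orientations. With no fold minimum, 9684 genes (70.3%) passed the ETV1 term, 4791 higher and 4893 lower. The scanner's own processed signals gave 810 genes past both thresholds, 396 higher and 414 lower, which puts 48.9% of the calls on the higher side against 38.5% here. Of 156 called genes with other kept probes, the other probes all passed in the same direction for 142, and for 6 another probe passed in the opposite direction. Adjusted over the list alone, the counts of members that rose and fell were identical for 20 of the 25 lists, with 23 against 22 higher for proteolysis and invasion, 12 against 11 higher for mesenchymal markers, 22 against 21 lower for the MAPK list, 2 against 1 lower for neuroendocrine markers and 7 against 6 lower for housekeeping genes.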

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

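The tests of the ETV1 probes, of histone genes and of dim probes with an offset of 0 were chosen only after results were seen, and the other tests before.

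Both ETV1 probes were lower in the RNA labelled RWPE-ETV1, the opposite of what overexpression would show at a probe within the expressed sequence. An exchange of RNA labels on some of the arrays would make those arrays oppose the rest, but the lowest correlation of turned ratios between any 2 arrays was 0.66. An exchange on all 4 arrays cannot be told apart from probes that lie outside the expressed sequence and follow the cell's own ETV1 transcript. The brighter probe changed by -0.66 and the dimmer by -0.58, and no probe positions were at hand to decide. The value for ETV1 was -0.86 with an offset of 0 and -1.02 with the scanner's processed signals. If the labels were exchanged on all 4 arrays, every direction given here would turn, proteases included.

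The fall of cell cycle genes was weighed next. The lowest median among 10000 random lists matched on brightness to the G2/M list was -0.27, against -1.65 for the list. Loess had already centred the ratios at each brightness on each array, so random medians near 0 were set in advance. The comparison shows only that no such fall with brightness remained after loess, and cannot speak against a bias of the raw ratios. A dye bias would change sign between orientations, but the highest of the 4 arrays' medians was -1.56. A lower share of cycling cells at harvest, from density or growth state, stays open: the replication-dependent histone genes had a median of -0.86, as it needs, but an effect of ETV1 on division would give the same. With RNA from 1 line of each kind these cannot be told apart.

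For 112 genes the ratio of RNA labelled RWPE-ETV1 over RWPE-GUS differed by at least 2-fold between the dye orientations, tested as the dye term of the fit, and 8 of them were among the called genes; with no fold minimum 5971 of 13771 genes passed the dye term, 187 of the 465 called genes among them. The differences between orientations of replicate 1 and of replicate 2 correlated at 0.86 across genes, as a dye bias of the probes or the place on the slide would give; genes are not independent replicates. These cannot be separated, since orientation coincides with the place on the slide, and separate RNA extracts per orientation were not tested. Weak signal of dim probes was first tested at the offset of 50, where 2.68% of these genes lay in the dimmest 25%, a share that by the limit set beforehand speaks against it. The test was then moved to an offset of 0, because an offset of 50 holds dim ratios near 0, and 29.5% of 173 such genes lay there, between the limits for and against it.

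In 5 of 130 sets of 4 turned ratios, 1 array stood apart from the other 3. Among 4 exchangeable arrays chance would flag about 1 in 20. These arrays form 2 pairs by dye orientation, so the chance rate here is unknown. For MMP9 and ADAM19 it was replicate 1 with RWPE-ETV1 in Cy5, at 2.51 against 2.33 to 2.36 and at 2.24 against 2.05 to 2.08. For FKBP5 the same array gave -1.58 against -1.07 to -0.99. For TWIST1 it was replicate 2 with RWPE-ETV1 in Cy3, at 0.43 against 0.64 to 0.68, and on that array the median of the basal markers was -0.081 against -0.30 to -0.27.

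Among probes without a gene symbol, which the comparison of genes does not use, 76 of 5905 tested changed by at least 2-fold at an adjusted p under 0.05 in limma, 38 higher and 38 lower.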

How the results depend on the processing

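ETV1 stayed lower and past the threshold in all 17 alternatives run, with log2 changes from -1.02 to -0.61. The number of changed genes stayed within 1.5 times of 465 in 17 of 22 alternatives, with a low of 406. Among these, quantile normalisation of brightness between arrays cannot change a ratio, and the deposited value table repeats the scanner's processed signals, so neither is a separate test. It was 810 with the scanner's processed signals and with the deposited value table (396 higher in both), 748 with the scanner software's error model per spot (356 higher), 1050 with limma's treat against 1.5-fold (472 higher, 578 lower), and 9684 with no fold minimum (4791 higher, 4893 lower). An offset of 0 gave 276 higher genes. A lower fold limit is built into treat and into no fold minimum. Leaving out each array in turn gave 453 to 468 genes, 169 to 185 higher and 270 to 290 lower. Without the cell cycle and DNA replication lists, a setting added after the data were seen, 422 genes changed, 179 higher and 243 lower.

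The 6 lists that passed camera kept their direction throughout, but the medians of 2 shrank: with no filter to 0.411 for proteolysis and invasion and 0.0977 for mesenchymal markers, and with probes tested singly to 0.417 and 0.159. With an estimated correlation they no longer passed, at unchanged medians of 0.63 for proteolysis and invasion, 0.41 for extracellular matrix, 0.26 for mesenchymal markers, -1.65 for G2/M, -0.66 for DNA replication and -0.43 for the MAPK list. That test has 2 degrees of freedom and also uses other correlations than the preset 0.01. The estimates were -0.031 for proteolysis and invasion and -0.022 for the MAPK list, both below the preset value. These values argue against a higher correlation having removed the calls of these 2 lists. The estimates were 0.044 for G2/M, 0.055 for DNA replication, 0.101 for extracellular matrix and 0.127 for mesenchymal markers. For these lists, whether the correlation or the degrees of freedom removed the calls was not tested. Mesenchymal markers also missed the threshold with both channels above background (median 0.24, adjusted p = 0.0613). Other lists gained a call, and the cause was not tested. With median centring these were integrins (0.31), basal markers (-0.25), TGF-beta targets (0.0546) and neuroendocrine markers (0.38). Averaging same-numbered arrays gained the same 4 lists (0.30, -0.23, 0.0389 and 0.34). With no filter they were basal markers (-0.23), epithelial junction (-0.13) and cholesterol synthesis (0.21), and with probes tested singly integrins (0.31), basal markers (-0.38), epithelial junction (-0.13) and cholesterol synthesis (0.21). Basal markers also gained a call without any 1 of 3 arrays, at medians between -0.30 and -0.17 over the 4 omissions (adjusted p 0.037 to 0.0964). Medians of 5 uncalled lists turned below 0 with no filter, and those of androgen metabolism with probes tested singly and of squamous differentiation without 1 array did so too. Of 1768 values for single named genes under alternatives, 13 no longer passed, all of FBLN1, CD68, CD14 or ACTB, and 0 changed sign.

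The labels give same-numbered arrays nothing in common but the number, and their deviations correlated at 0.21 across genes, which with 2 pairs leaves open whether they share an RNA extract. With the replicate number as a block, 465 genes changed, 179 higher and 286 lower, and no list or named gene changed its call. A slide or scan block was not run, since all arrays shared both. Dim probes near background limit what could be tested: 26016 of 41000 probes were kept.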

Other observations

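The groups below were picked after some of their members were seen among the changed genes. The test of other glucocorticoid targets and those of neighbouring genes and of array splits were set before their results were seen. The exception is that the glucocorticoid targets were already known not to be among the changed genes.

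Histone genes fell together. All 58 measured genes of the replication-dependent histone clusters were lower, 18 of them at least 2-fold, with a median log2 change of -0.86 and medians from -0.98 to -0.83 under 4 other scalings. Beside H1-1, H4C3 fell 4.08-fold (-2.03, SE 0.0858). Near-identical copies share probe signal, so single histone genes are uncertain. Metallothionein genes, which encode metal-binding proteins, behaved alike: 9 of 10 measured fell, each at least 2-fold, and MT1F rose 1.13-fold (median -1.20). MT1M fell 3.03-fold (-1.60, SE 0.0423) and MT2A 2.19-fold (-1.13, SE 0.0496). The MT2A ratios were -0.60 and -0.36 with RWPE-ETV1 in Cy5 and -1.87 and -1.70 with it in Cy3, and 9 of the 10 genes passed the dye term, as 5971 of 13771 genes did. The 9 that fell were lower on every array measured. These copies resemble each other, so single genes are uncertain.

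Outputs of the circadian clock were lower as well. Of 10 measured genes, 9 fell and PER3 did not pass (median -0.73, -1.05 to -0.71 under 4 other scalings). PER1 fell 2.71-fold (-1.44, SE 0.0509), DBP 2.64-fold (-1.40, SE 0.0437) and NR1D1 2.62-fold (-1.39, SE 0.0396), each lower on all 4 arrays.

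PER1, FKBP5 and DUSP1 are also induced by glucocorticoids, and a lower glucocorticoid response in the RNA labelled RWPE-ETV1 was set up as a hypothesis. Of 14 other known glucocorticoid targets, known beforehand not to be among the changed genes, 11 were measured. The median log2 change was -0.54, and 3 of 10000 random lists matched on brightness had a median as low. The random lists draw genes singly, so this count ignores any correlation between the targets. By the same count, 2 of 10000 random lists were as high as the integrin and hemidesmosome list, which did not pass camera. Camera was not run on the glucocorticoid targets. RGS2 (-0.998, SE 0.0425), PDK4 (-0.90, SE 0.0485) and TSC22D3 (-0.88, SE 0.0491) fell most, and SGK1, SLC19A2 and ELL2 rose (0.16, 0.14 and 0.13). The SLC19A2 ratios were 0.46 and 0.42 with RWPE-ETV1 in Cy5 but -0.03 and -0.30 with it in Cy3. Of the 11 targets, 7 passed the dye term, as 5971 of 13771 genes did. The values of these targets are compatible with the hypothesis. They may equally follow a difference in time since feeding or in density between the cultures, which the labels do not record, and some of these genes also follow the clock.

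Genes that neighbour each other on a chromosome changed together. Over 12793 protein-coding genes in RefSeq order, Spearman's rho of the log2 change was 0.0984 for adjacent genes and 0.0329 for genes 10 apart, across genes that are not independent. The highest of 1000 shuffles of gene order reached 0.0277 for adjacent genes, and 1 of 1000 was as high as the observed value for genes 10 apart. Without the histone genes the values were 0.0895 and 0.0282. A small contribution of regional differences between the lines, of copy number or of expression, is compatible with this. Shuffling gene order breaks any likeness between neighbours, and only the histone genes were left out. Other neighbouring genes that resemble each other or are regulated together could therefore give the same, and the test does not separate these.

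The 4 arrays can be split 2 against 2 in 3 ways, with the dye term kept. The real assignment (1 of the 3) gave 465 genes and the highest of the others 0, where limma found 7 genes at an unadjusted p under 0.05. In the other splits the difference between the 2 RNAs falls into the residual spread, so few calls there were set in advance. The comparison is therefore no evidence for the 465 genes, and so few splits cannot give a share under 0.05.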
